A study of Drosophila melanogaster with 48 samples.

How the data were processed

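Total RNA of Drosophila melanogaster females and males was compared on printed 2-colour oligonucleotide arrays. The 48 samples fell into 8 groups of 6, defined in the labels by hybrid genotype (genotype 1, from a cross of We61 females with We29 males, or genotype 2, from We32 females with We107 males), by sex and by larval diet (high or low). The composition of the diets, the age of the flies and the tissue were not given in the sources used here. Each of the 24 arrays carried a sample labelled with Alexa555 and another labelled with Alexa647, joined in a loop with no common reference. Each of the 6 temporal blocks held 4 arrays and 1 genotype, so blocks 1 to 3 were genotype 1 and blocks 4 to 6 were genotype 2. In every block 2 arrays carried samples of 1 sex with different diets, called same-sex arrays here. The other 2 carried a female and a male sample of the same diet, called mixed-sex arrays.

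The deposited scanner tables gave, per the file headers, a spot intensity on a linear scale in each channel with its local background, from an adaptive quantification and with no background subtraction. The tables under the 2 samples of an array were identical for all 24 arrays, and each channel was read once. The image names in the file headers carried the sex, diet and dye of the label in all 48 channels. The authors also deposited a table of processed log2 values with a column per sample, which served as an alternative. Limma and R 2.7.1 are named in the submitters' processing notes, and the steps behind that table were not given in the sources used here. Its columns all had a mean of 8.12 and medians of 7.62 to 7.70, so they had been brought to a common level. Each column correlated best with the log2 intensity of its own channel, at 0.840 to 0.998, which settles the direction and a log2-like scale but not the exact scaling.

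Each array held 32448 spots, which are 16224 probes printed as 2 adjacent spots in 48 subgrids. Of these probes, 14439 were named by a CG or CR number and 1785 were controls or blanks. The 13820 distinct numbers were matched to a gene table named for the assembly Release 6 plus ISO1 MT, 12047 by locus tag and 1153 by a single synonym (95.5%). A further 189 matched several genes and 431 matched none, and these kept their number as their name. Median spot intensity per sample ranged from 86.8 to 513. Between 69.7% and 97.3% of gene spots lay above their local background by over 2 background standard deviations, but so did 56.8% to 87.9% of blank spots. Between 10.7% and 51.6% of gene spots exceeded the 95th percentile of the blank spots. Between 0 and 3258 spots of a sample had an intensity of 0, and 7 arrays had over 1% of such spots in a channel.

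Background was corrected by normexp with an offset of 50, spots marked bad by the scanner software were left out, and dye bias was removed by global loess within each array with control spots at weight 0. Mean intensities were then made equal in distribution between arrays (Aquantile) and duplicate spots were averaged. A probe was kept if both of its spots lay above background in at least 4 of the 6 samples of at least 1 group, which removed 2 probes. Each gene was represented by its probe with the highest mean, which mattered for 869 genes with several probes, and 13295 genes were tested. The fits used limma 3.58.1 and statmod 1.5.0 in R 4.3.3, tables were read with version 1.17.8 of data.table, and figures were drawn with matplotlib 3.10.9 in python 3.11.15. The log2 values of all 48 samples entered 1 linear model with the 8 groups, dye and temporal block, and the array as a random block with a correlation of 0.703. Moderated tests had 35 residual and 2.42 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as a call. Sex is given as female minus male, diet as high minus low, and interactions as genotype 2 minus genotype 1 or female minus male. Because a block holds 1 genotype, the genotype effect was tested with limma on the means of the 6 blocks, 3 against 3, and block and genotype cannot be told apart beyond the spread between blocks.

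The temporal block stood in the model because the labels name it. Deviations of samples from their group mean had a median correlation of 0.741 between the samples of an array and of 0.0945 (range -0.632 to 0.606) between different arrays of a block, against -0.00833 (range -0.527 to 0.550) between genotypes. The median of -0.157 between blocks of a genotype is lowered by the centring on group means, so it is no baseline. Leaving the block out of the model gave 7949 calls for sex and 43 for genotype by sex. The labels call the samples biological but name no separate cultures or collections, so the p-values measure the spread between these samples. The number of arrays limits the precision. The fits were tested on simulated data with 50 changed genes of each size among 13159. Changes of 1.5-fold were called in 94% of cases for sex, 84% for diet in females, 84% for diet in males, 58% for genotype by sex and 12% for genotype. Changes of 2-fold were called in 98%, 100%, 98%, 96% and 70% of cases. The simulated noise was normally distributed, with 1 array correlation for all genes and no spread of effects between blocks. These shares may therefore be too high for the real data.

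A total of 26 gene lists were written from textbook knowledge before the data were examined. They cover yolk, eggshell, oocyte, accessory gland, testis, sex determination, male-enriched fat body, insulin and TOR signalling, lipid, carbohydrate, larval serum, immune, hemocyte, heat shock, detoxification, digestive, muscle, phototransduction, odorant-binding, neuronal, cytoplasmic and mitochondrial ribosomal, respiratory chain, cell cycle, cuticle and yolk uptake genes, and include markers of several tissues because the labels name none. Members were matched by symbol or by an unambiguous synonym; this matching rule was refined after the gene names of the arrays were known and before any list result was seen. Lists were tested with cameraPR on the moderated statistics at a preset correlation of 0.01 and again with a correlation estimated from residuals, and their p-values were adjusted over the 26 lists. Some genes stand in several lists. For the median diet effect of sex-biased classes, the high minus low difference was taken per block and tested by an exact two-sided sign-flip permutation test over 6 blocks, with 64 sign patterns and a smallest possible p of 0.0312.

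The groups, the tests, the lists, the processing alternatives and the rule for naming genes were fixed before the data were examined. The rule took, for sex, diet, sex by diet and genotype, the 5 genes in each direction with the largest change among the called genes that carry a proper symbol and keep their sign in every block, up to 3 genes of each list that passed its test and 1 of each other list, and the yolk protein genes, the roX RNAs and the sex peptide gene as checks of sex. The text names part of the genes the rule gives. Genes named for the genotype interactions, CR32368, CG9978, CG14499, CG10700 and the genes displaced in a temporal block were chosen after their values were seen. Where a gene was below the 95th percentile of the blank spots in all samples of the dimmer sex, its fold is a bound: the mean of the brighter sex was set against the mean of the per-array floor of detected signal, or of the probe's own value where that was higher. Where the dimmer sex exceeded the blank spots on mixed-sex arrays alone, the bound was taken in the same way from same-sex arrays, a step added after the results were seen. For CG10700 it was taken between the genotypes. Alternatives to the background correction, both normalizations, the filter, the probe choice, the model and the samples used were run, and 9 further ones were added after the data were seen: leaving out spots at 0, a filter against blank spots, leaving out the 7 arrays with many spots at 0, the day of image quantification in place of the block, same-sex arrays alone, mixed-sex arrays alone, leaving out the genes of 1 print subgrid, leaving out genes displaced in 1 block, and tests of interactions with genotype on block means. Scanner columns other than intensity, background, its standard deviation and the quality mark were not used here.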

Results

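Transcript levels of female and male Drosophila melanogaster were measured in 48 samples from 24 arrays, to ask how far the difference between the sexes depends on the larval diet. The samples formed 8 groups of 6, which combined 2 hybrid genotypes, 2 sexes and a high or low larval diet. Every group had 3 temporal blocks with 2 samples in each. Values are log2 intensities of 13295 genes, and the number of arrays limits the precision.

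The 1st question was which genes differ between females and males. In the fit of all arrays the largest female excess was that of the deadhead gene dhd (CG4193), a thioredoxin of the female germ line, at least 75.1-fold (fitted log2 difference 5.73, SE 0.120, adjusted p = 8.82e-32 by limma, n = 24 per sex, 6 of 6 blocks). A fold given as at least N-fold is a bound, because the dimmer sex did not exceed the blank spots in any sample, or in any of its 12 samples on arrays with samples of 1 sex. In the latter case the bound comes from those arrays alone. Bounds rest on means of samples and not on the fit, so in either case they can exceed the fitted difference of all arrays. They allow for the unresolved level of the dimmer sex alone, and not for the spread between samples. Where the detection floor lay below the probe's own values, the bound is the plain estimate of those arrays. For EbpII, below, it equals the log2 difference of -6.91 on same-sex arrays, the largest in a range of -6.91 to -5.69 over the settings run. Yp1 (CG2985), Yp2 (CG2979) and Yp3 (CG11129), which encode the yolk proteins, were at least 80.6-, 52.6- and 45.2-fold higher in females. The largest male excess in that fit was that of EbpII (CG2665), an ejaculatory bulb protein gene, at least 121-fold (fitted log2 difference -5.98, SE 0.145, adjusted p = 1.15e-29). Mst57Db (CG5016) and Mst57Da (CG9074), which encode male accessory gland peptides, were at least 111- and 96.9-fold higher in males, and Anp (CG1361), the antibacterial peptide andropin of the ejaculatory duct, at least 68.4-fold. The other genes with the largest fitted differences were Muc12Ea (CG32602, a mucin) and ldd (CG32516), at least 37.2- and 37.3-fold, and Snrk (CG8485, a protein kinase), at 35.4-fold, in females, and Met75Cb (CG18064) in males, at 42.7-fold. All of these kept their direction in 6 of 6 blocks.

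As a check of the labels, the sex peptide gene SP (CG17673), whose product is passed to females at mating, was at least 27.1-fold higher in males, because it did not exceed the blank spots in any female sample. The dosage compensation RNA lncRNA:roX1 (CR32777) was at least 19.6-fold higher in males, where the fit gave 17.5-fold. For lncRNA:roX2 (CR32665), from the same complex, the fit gave 1.78-fold (adjusted p = 1.88e-06 by limma). It exceeded the blank spots in only 6 of 24 males and in 0 females, so its fold is not resolved and no bound is given. The first principal component held 39.1% of the variance and had all 24 female samples below 0, the highest at -5.68, and all 24 male samples above 0, the lowest at 11.7.

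Gene lists fixed beforehand moved as sets. Of 22 eggshell genes, 21 were called higher in females (adjusted p = 1.51e-23, or 0.00135 with an estimated correlation), among them the chorion genes Cp36 (CG1478, at least 34.3-fold) and Cp16 (CG6533, at least 32.9-fold) and the vitelline membrane gene Vm26Aa (CG9048, at least 15.3-fold). All 3 yolk genes were higher as a list too (adjusted p = 6.7e-16, or 2.97e-06 with an estimated correlation). Of 34 oocyte determinants, 28 were higher and 1 was lower in females (29 and 2 when adjusted over the list alone; adjusted p = 5.2e-14, or 0.00199 with an estimated correlation). They included osk (CG10901), which assembles the germ plasm, at least 17.3-fold, the mitotic cyclin CycB (CG3510), at least 13.7-fold, and gcl (CG8411), needed for pole cell formation, at 2.76-fold. Of 33 accessory gland genes, 29 were higher in males and 1 in females (adjusted p = 2.66e-65, or 2.03e-08 with an estimated correlation), with Ebp (CG2668) at 29.7-fold. Of 76 testis genes, 62 were higher in males and 3 in females (63 and 3 over the list alone; adjusted p = 2.4e-22, or 0.0162 with an estimated correlation). Mst87F (CG17956), a sperm-tail protein gene, was at least 35.6-fold higher, and the sperm aminopeptidase genes loopin-1 (CG4750) and S-Lap7 (CG13340) at least 29.4- and 15.4-fold.

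At the preset correlation, lists of ribosomal, cell cycle and insulin or TOR genes were higher in females. Of 86 cytoplasmic ribosomal protein genes, 77 were higher and 5 lower, with a median difference of 1.06 on the log2 scale (adjusted p = 4.21e-23, or 3.65e-05 with an estimated correlation). RpS5b (CG7014), a ribosomal paralogue of the ovary, was at least 15-fold higher and RpS12 (CG11271) 2.61-fold. Of 53 cell cycle genes, 52 were higher and 0 lower (adjusted p = 2.95e-14, but adjusted p = 0.0925 with an estimated correlation), including the replication clamp PCNA (CG9193, 3.88-fold), CycA (CG5940, 4.54-fold) and the ribonucleotide reductase subunit RnrS (CG8975, at least 4.78-fold). Of 69 mitochondrial ribosomal genes, 47 were higher and 1 was lower (49 and 1 over the list alone; adjusted p = 4.82e-05, but 0.110 with an estimated correlation). The gene mRpS33 (CG10406) was 2.10-fold higher in females, mRpL22 (CG4742) at least 1.39-fold, and the exception mRpS14 (CG32531) 2.15-fold higher in males, in 5 of 6 blocks. Of 28 insulin and TOR genes, 14 were higher and 3 lower (15 and 3 over the list alone; adjusted p = 0.0414, but 0.0925 with an estimated correlation). The cap-binding factor eIF4E1 (CG4035) was 2.62-fold higher, the amino acid transporter slif (CG11128) at least 1.56-fold and the TOR complex gene Lst8 (CG3004) at least 1.52-fold. In females slif exceeded the blank spots in 14 and Lst8 in 17 of 24 samples, so these folds are not fully resolved. On same-sex arrays alone the bound of slif was 1.38-fold. This list call was lost in 11 of 30 settings, among them same-sex arrays alone (adjusted p = 0.112) and the filter against blank spots (adjusted p = 0.199), and ranged from 0.0291 to 0.199 over them.

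At the preset correlation, lists of muscle, carbohydrate, respiratory chain and detoxification genes were higher in males. Of 31 muscle genes, 29 were higher in males and 1 in females (adjusted p = 9.38e-11, or 0.0238 with an estimated correlation). Myosin heavy chain Mhc (CG17927) was 3.44-fold higher, the troponin I gene wupA (CG7178) 2.89-fold and tropomyosin Tm2 (CG4843) 2.67-fold. Of 43 carbohydrate genes, 29 were higher in males and 2 in females (30 and 2 over the list alone; adjusted p = 1.29e-05, or 0.0354 with an estimated correlation), including the maltases Mal-A1 (CG8696, 4.2-fold) and Mal-A6 (CG30360, 3.28-fold) and the glycolytic enzyme Pglym78 (CG1721, 4.19-fold). Of 86 respiratory chain genes, 73 were higher in males and 1 in females (75 and 1 over the list alone; adjusted p = 6.81e-08, but 0.103 with an estimated correlation). The list median was -0.54, and its members COX4L (CG10396, at least 4.46-fold), COX7AL (CG18193, at least 4.50-fold) and UQCR-11L (CG30354, at least 2.23-fold) are paralogues of the general subunits. Of 116 cytochrome P450 and glutathione transferase genes, 57 were higher in males and 8 in females (adjusted p = 0.00174, but 0.102 with an estimated correlation). They included Cyp313a5 (CG15807, 5.29-fold), the hydrocarbon synthesis gene Cyp4g1 (CG3972, 3.13-fold) and the insecticide resistance gene Cyp6g1 (CG8453, 2.91-fold).

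Sensory and neuronal lists were also higher in males at the preset correlation. Of 55 odorant-binding and chemosensory genes, 30 were higher in males and 2 in females (adjusted p = 1.02e-06, or 0.0162 with an estimated correlation). Obp56g (CG13873), whose product is also a seminal fluid protein, was at least 40.0-fold higher, Obp56d (CG11218) 3.42-fold and Os-C (CG3250) 3.07-fold, and the list shares PebIII with the accessory gland list. Of 25 phototransduction genes, 16 were higher in males and 2 in females (adjusted p = 0.000747, but 0.0989 with an estimated correlation), with the retinol dehydrogenase gene Pdh (CG4899) at 2.67-fold and the arrestins Arr2 (CG5962) and Arr1 (CG5711) at 2.41- and 2.39-fold. Of 28 neuronal genes, 21 were higher in males and 1 in females (adjusted p = 0.00254, but 0.199 with an estimated correlation). The sodium pump subunit nrv3 (CG8663) was 2.61-fold and the neuropeptide gene Dh31 (CG13094) 1.80-fold higher in males, whereas the GABA receptor gene Rdl (CG10537) was 1.59-fold higher in females.

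The remaining 10 lists did not pass the test. Among 49 immune genes 6 were higher and 23 lower in females (adjusted p = 0.148), and the Toll-induced peptide gene Dso1 (CG15231) was 2.67-fold higher in males. Of 30 lipid genes, 5 were higher and 14 lower (15 lower over the list alone; adjusted p = 0.0884), with the sterol-binding Npc2b (CG3153) 2.42-fold higher in males. Called members went both ways in the lists of larval serum proteins (2 higher and 2 lower of 6, adjusted p = 0.892), digestive proteases (9 and 8 of 30, adjusted p = 0.892), heat shock (6 and 9 of 18, adjusted p = 0.434), yolk uptake and transport (2 and 6 of 9, adjusted p = 0.431) and cuticle proteins (15 and 28 of 132, or 13 and 25 over the list alone, adjusted p = 0.771). Median, mean and test differed in sign for sex determination (median 0.18, mean -0.15, 9 higher and 4 lower of 17, or 10 and 4 over the list alone, adjusted p = 0.827), male-enriched fat body genes (median -0.24, mean 0.07, 4 and 6 of 10, adjusted p = 0.911) and hemocyte markers (median -0.03, mean 0.06, 2 and 4 of 14, adjusted p = 0.907). Single genes of these lists still differed: the female pheromone desaturase Fad2 (CG7923) was at least 5.51-fold and the GATA factor gene srp (CG3992) at least 2.50-fold higher in females, while the transferrin gene Tsf1 (CG6186) and the cuticle gene Cpr57A (CG18066) were 3.31- and 4.76-fold higher in males.

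**Figure D1:**
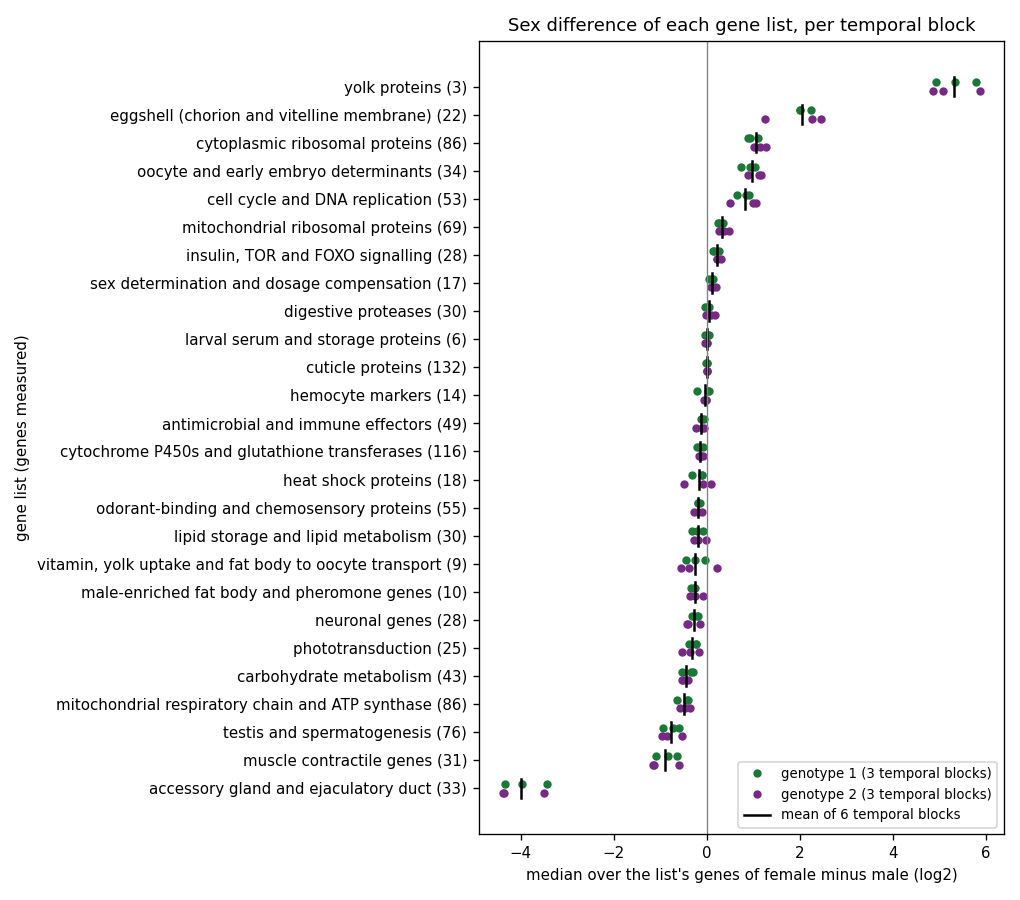
Each row is a gene list with the number of its genes measured, and each point is the median over those genes of the female minus male difference (log2) in 1 temporal block, with the mean of 6 blocks as a black line. The yolk list lay between 4.85 and 5.87 and the accessory gland list between -4.39 and -3.44 over the 6 blocks.

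In all, 8077 of 13295 genes were called for sex by limma, 4035 higher in females and 4042 higher in males, of which 451 and 743 differed at least 2-fold. Loess within mixed-sex arrays and Aquantile between arrays set the sexes to a similar level, so the even counts are in part built in. The median sex difference over all genes was -0.000398. Differences are relative to all signal of a sample. As the tissue was not named, shares of tissues were not told apart from expression within them. The counts were 6115 in genotype 1 and 6565 in genotype 2, and the sex effects of the genotypes correlated at 0.958 across genes, which are not independent replicates. Among genes at least 2-fold higher in females, 90 of 449 lay on the X chromosome, against 1957 of 12226 other genes (odds ratio 1.32, 95% interval 1.03 to 1.67, two-sided Fisher's exact p = 0.0262). Among those at least 2-fold higher in males, 73 of 711 did, against 1974 of 11964 (odds ratio 0.579, interval 0.446 to 0.743, exact p = 4.69e-06). In both tests the other genes include those near the level of blank spots and the class biased to the opposite sex. The tests also take genes as independent. Whether the share of detected genes differs between chromosomes was not tested. Same-sex arrays alone called 5194 genes. Only 5718 of the 14439 probes exceeded the blank spots in at least 4 of 6 samples of a group. With the filter against blank spots 4550 genes were called, so many of the 8077 calls fell on genes without signal above the blank spots by this measure.

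Sex-specific genes were brighter in the opposite sex where a female and a male sample shared an array. The yolk genes had a mean log2 intensity of 7.97 (SD 0.0956, n = 12) in males on same-sex arrays and of 9.59 (SD 1.09, n = 12) on mixed-sex arrays, and the accessory gland genes of 8.29 (SD 0.0706) and 8.80 (SD 0.399) in females. The fitted sex differences above include both kinds of array. Snrk, Met75Cb, mRpS14, Npc2b, Os-C and Cpr57A exceeded the blank spots in 1 to 5 of 12 samples of the dimmer sex on same-sex arrays, so their folds are not fully resolved. On same-sex arrays alone the log2 difference was 6.68 for Yp1, 6.61 for dhd and -6.91 for EbpII, against 5.09, 5.73 and -5.98 in the fit of all arrays, so Yp1 and dhd changed places.

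**Figure D2:**
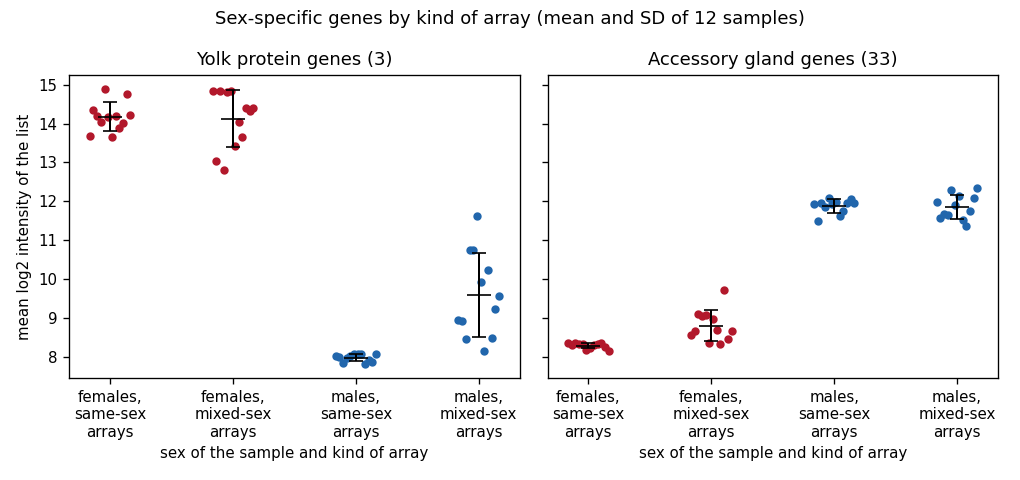
Points are the mean log2 intensity of the 3 yolk protein genes (left) and of the 33 accessory gland genes (right) in each sample, by sex and by whether its array carried samples of 1 sex or of both, with mean and SD of 12 samples. Males on mixed-sex arrays lay between 8.14 and 11.6 for the yolk genes, against 7.80 to 8.07 on same-sex arrays.

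The 2nd question was which transcripts of females depended on the larval diet. Npc2e (CG31410), a gene of the NPC2 family of sterol-binding proteins, fell by 0.57 on the log2 scale from low to high diet in females (SE 0.0942, adjusted p = 0.00635 by limma, n = 12 per diet, lower in 6 of 6 blocks). The sign carries little weight in genotype 2, where its blocks gave -0.0227, -0.00267 and -0.127. In genotype 1 they gave -0.36, -0.80 and, in block 3, -2.12. The noncoding RNA gene lncRNA:CR32368 (CG32368) fell by 1.22 (SE 0.220, adjusted p = 0.0162). In genotype 1 Npc2e had a mean of 9.29 (SD 0.763, n = 6) on the low and 8.19 (SD 0.245) on the high diet, against 8.17 (SD 0.219) and 8.12 (SD 0.115) in genotype 2, while lncRNA:CR32368 had 9.95 (SD 1.19) and 7.94 (SD 0.308) in genotype 1. Npc2e exceeded the blank spots in 5 of 6 low-diet and 2 of 6 high-diet females of genotype 1 and in 0 of those of genotype 2. For lncRNA:CR32368 it was 5 of 6 and 1 of 6 low-diet females of genotypes 1 and 2 and 0 high-diet females, so the size of neither difference is resolved. The interaction of genotype and diet itself did not pass for Npc2e (0.78, SE 0.15, adjusted p = 0.0732) or for lncRNA:CR32368 (1.56, adjusted p = 0.119). GstD10 (CG18548), a glutathione transferase gene, was not called at -0.84 (SE 0.231, adjusted p = 0.754), with the same sign in 6 of 6 blocks, and exceeded the blank spots in 0 high-diet females.

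No other gene was called in females, although 410 had an unadjusted p under 0.05, where 665 are expected by chance. With the high diet 3 lists rose as sets at the preset correlation: eggshell genes (17 of 22 positive, median 0.12, adjusted p = 0.0138), oocyte determinants (24 of 34 positive, median 0.06, adjusted p = 0.0248) and cytoplasmic ribosomal proteins (69 of 86 positive, median 0.07, adjusted p = 0.0138). Each had adjusted p = 0.818 with an estimated correlation and 0 members called, over all genes or adjusted over the list alone. Among their members, none of which was called, were the oogenesis transcription factor gene ovo (CG6824, 0.43, SE 0.157), the eggshell genes Cp18 (CG6517, 0.40, SE 0.202) and yellow-g (CG5717, 0.40) and the ribosomal genes RpL22 (CG7434, 0.30) and RpS5b (0.25). The direction turned in genotype 1 alone for the eggshell (adjusted p = 0.656) and ribosomal lists (adjusted p = 0.809), and without the 7 arrays with many spots at 0 for the oocyte list (adjusted p = 0.49). Yp1 (0.17, SE 0.256) and the yolk receptor gene yl (CG1372, 0.33) were not called either. In the lipid list 1 of 30 genes fell, Npc2e, and the other 22 lists had 0 called members; the median and the mean of the mitochondrial ribosomal list differed in sign. Over the temporal blocks left out in turn the count of 2 went from 0, without block 2, 4, 5 or 6, and 1 without block 3 to 10 without block 1. Both calls were lost with quantile normalization and in the fit of log-ratios, where limma called 0 genes.

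In males 0 genes were called for diet by limma, with 293 at an unadjusted p under 0.05. GstD10 (-1.08, SE 0.231, negative in 6 of 6 blocks) and lncRNA:CR32368 (-1.09, SE 0.220) had the smallest adjusted p, at 0.207 each, and Npc2e had 0.637 (-0.37, SE 0.0942). The list of immune effectors rose with the high diet (adjusted p = 2.11e-08, or 0.0321 with an estimated correlation), with 33 of 49 genes positive, a median of 0.06, a mean of 0.17 and 0 members called over all genes or adjusted over the list alone. Its largest values were those of the antimicrobial peptide genes Mtk (CG8175, 0.85, SE 0.250), AttA (CG10146, 0.82, SE 0.271) and AttC (CG4740, 0.77, SE 0.249). In genotype 1 males Mtk had means of 9.13 on the high and 9.33 on the low diet, AttA of 9.12 and 9.15 and AttC of 8.46 and 8.32. In genotype 2 males they were 9.74 and 8.51, 9.83 and 8.65, and 9.22 and 8.11. Over 27 settings the values went down to 0.0781 for Mtk, 0.124 for AttA and 0.0874 for AttC. This list call was lost in genotype 1 alone (adjusted p = 0.299) and without the 7 arrays with many spots at 0 (adjusted p = 0.0524), with a range of 1.57e-24 to 0.299 over 28 settings. The storage protein gene Lsp2 (CG6806, 0.41), Tsf1 (0.43), Yp1 (-0.40) and the chorion gene Cp19 (CG6524, -0.31) were not called. Adjusted over the list alone, 1 lipid gene and 1 P450 or glutathione transferase gene fell. Median, mean and test differed in sign for the accessory gland, sex determination, P450 and cuticle lists. Alternative settings called 0 to 3 genes, and 11 were called without block 1.

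With both sexes averaged, 5 genes fell from low to high diet and 0 rose, with 322 at an unadjusted p under 0.05. Chosen after their values were seen, they were lncRNA:CR32368 (-1.15, SE 0.174, adjusted p = 0.00116), Npc2e (-0.47, SE 0.0748, adjusted p = 0.00166), CG9978 (-0.69, SE 0.124, adjusted p = 0.0102), GstD10 (-0.96, SE 0.183, adjusted p = 0.0221) and CG14499 (-0.85, SE 0.172, adjusted p = 0.0439). These calls depended on single blocks: the count was 13 without block 1, 1 without block 3 or 4 and 0 by limma without block 2, 5 or 6 (351, 275 and 305 unadjusted). By block lncRNA:CR32368 was at -2.54 and -3.37 in blocks 2 and 3 and between -0.39 and 0.05 in the others, and Npc2e at -1.90 in block 3 and between -0.65 and 0.07 in the others. GstD10 had means of 9.27 (SD 1.09) on the low and 8.31 on the high diet in females of genotype 1, and 9.22 (SD 1.18) and 8.10 in those of genotype 2. Its highest low-diet values in genotype 2 came from 1 mixed-sex array of block 4 (male 10.52, female 9.90) and 1 of block 6 (male 10.88, female 11.22). The other low-diet samples of genotype 2 lay between 8.12 and 9.18. Because a female and a male of the same diet share such an array, the 2 sexes are not independent here. In the fit of all samples, the diet effect within genotype 1 had 4 genes lower in females and 4 lower and 1 higher in males, and within genotype 2 it had 0 in each sex, with 411 and 236 genes at an unadjusted p under 0.05. Fitted on the samples of genotype 1 alone, limma called 0 genes in each sex. The diet effects of the sexes correlated at 0.155 across 13159 genes (Spearman 0.122, covariance 0.00109), below the mean of 0.260 (0.236 to 0.282, covariance 0.00325) of 1000 simulations of the estimates on these arrays with no diet effect. Each gene was drawn independently there, whereas real genes deviate together within arrays. The interval is therefore too narrow to judge the difference, and no conclusion is drawn from it.

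**Figure D3:**
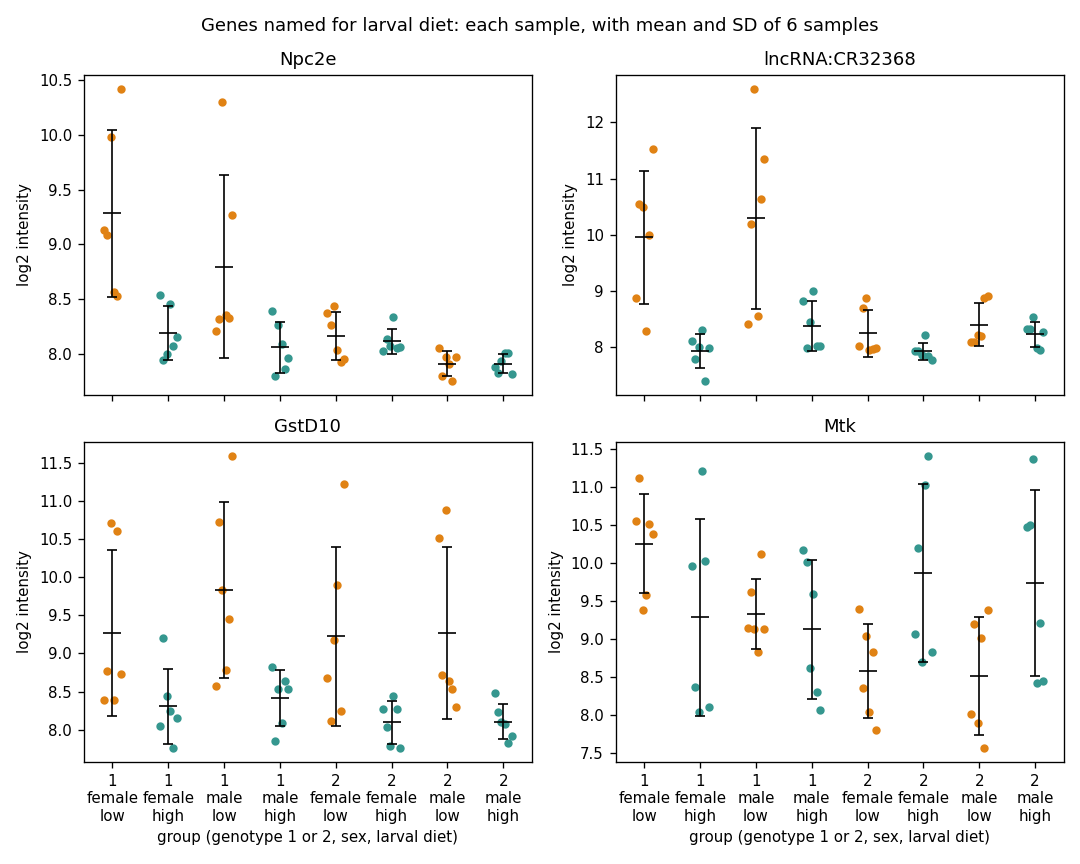
Each panel shows 1 gene, with the log2 intensity of every sample by genotype, sex and larval diet (orange, low; teal, high) and the mean and SD of 6 samples. Npc2e and lncRNA:CR32368 were highest in the low-diet groups of genotype 1 (lncRNA:CR32368 means 9.95 in females and 10.29 in males). GstD10 was higher on the low diet in all 4 pairs of groups, but females and males of the same diet share the mixed-sex arrays, so these pairs are not independent. Mtk went from 8.58 to 9.87 in genotype 2 females and from 10.25 to 9.28 in genotype 1 females.

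The 3rd question, named in the title of the series, was whether sex-biased expression changes with condition. Genes at least 2-fold higher in females had a median high minus low difference of 0.203 in females over the 6 blocks (SD 0.154, positive in 5 of 6, exact sign-flip permutation p = 0.0625) and of -0.0164 in males (SD 0.231, exact p = 0.969). The difference between the sexes was 0.219 (SD 0.313, exact p = 0.156). Genes at least 2-fold higher in males had 0.0856 in males (SD 0.265, exact p = 0.438) and 0.0130 in females (SD 0.314, exact p = 0.906), with a difference of -0.0727 (SD 0.554, exact p = 0.75). None of these exact tests gave a p under 0.05, where the smallest they allow is 0.0312. With the authors' table in place of this processing, the test of male-biased genes in males did pass. The spread lay on the mixed-sex arrays: the male-biased class in females had an SD over blocks of 0.0228 on same-sex and 0.632 on mixed-sex arrays, and the female-biased class in females had means of 0.0484 (SD 0.0395) and 0.340 (SD 0.300). The median of the male-biased class in females turned to -0.0149 on same-sex arrays. Within a sex and a kind of array each diet had 1 dye, and the other kind had the dyes reversed, so these values do not part diet from dye. Diets were compared within an array on same-sex arrays and between arrays on mixed-sex arrays. Samples of an array deviate together (correlation 0.703), so a wider spread on mixed-sex arrays is in part built into the design. Genes of the opposite sex also lay near the floor on same-sex arrays.

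**Figure D4:**
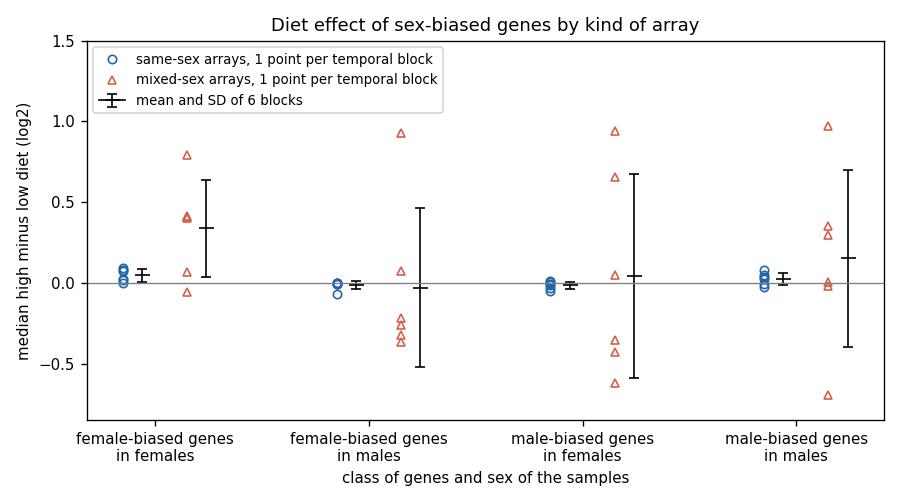
Points are the median high minus low difference (log2) of female-biased and male-biased genes in 1 temporal block, for each sex and each kind of array, with mean and SD of 6 blocks beside them. The SD of the male-biased class in males was 0.0376 on same-sex arrays and 0.547 on mixed-sex arrays.

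Tested gene by gene, the sex by diet interaction had 0 calls by limma, with 314 genes at an unadjusted p under 0.05 and a smallest adjusted p of 1.00. At the preset correlation 7 lists differed in their diet effect between the sexes. Eggshell (18 of 22 positive, adjusted p = 0.00338), oocyte (25 of 34, adjusted p = 0.0168) and ribosomal lists (73 of 86, adjusted p = 0.00338) were shifted towards a higher diet effect in females. Testis (adjusted p = 0.0168), larval serum (adjusted p = 0.0438), immune (adjusted p = 0.00338) and odorant-binding lists (adjusted p = 0.0137) were shifted towards males. With an estimated correlation none passed, with adjusted p = 0.644 for eggshell, oocyte, ribosomal, immune and odorant-binding genes, adjusted p = 0.751 for testis and adjusted p = 0.256 for larval serum genes, and 0 members were called over all genes or adjusted over the list alone. Values of single genes, none of them called, were Yp1 (0.57, SE 0.311), Cp36 (0.52), ovo (0.46), RpS5b (0.34) and RpS2 (CG5920, 0.28) on the female side and the stress peptide gene TotA (CG31509, -0.72), Lsp2 (-0.45) and Obp56d (-0.36) on the male side. On mixed-sex arrays the genes of the opposite sex were brighter, as given above for the yolk and accessory gland lists. Without the 7 arrays with many spots at 0, the shifts of the eggshell (adjusted p = 0.279), oocyte (adjusted p = 0.00235, range over 28 settings 3.25e-05 to 0.942), testis (adjusted p = 1.15e-05, range 5e-06 to 0.905) and odorant-binding lists (adjusted p = 0.804) turned around. In genotype 1 alone those of the eggshell (adjusted p = 0.0914), oocyte (adjusted p = 0.942) and testis lists (adjusted p = 0.892) did. Median, mean and test differed in sign for the hemocyte, phototransduction and respiratory chain lists.

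The 4th question was whether the sex difference depends on the genotype. The female minus male difference of the glycolytic gene Pglym78 was -1.27 in genotype 1 and -2.86 in genotype 2 on the log2 scale, an interaction of -1.58 (SE 0.282, adjusted p = 0.00246 by limma). The vesicle transport gene Rab26 (CG32439) had an interaction of -1.75 (SE 0.340, adjusted p = 0.00556) and mRpS14 of -1.18 (SE 0.273, adjusted p = 0.0352). The largest interactions among called genes were those of CG31998 (-2.42, SE 0.295, adjusted p = 9.55e-06), whose sex difference went from 0.33 in genotype 1 to -2.09 in genotype 2, and of CG5070 (2.35, SE 0.313, adjusted p = 2.51e-05), which went from -1.13 to 1.21. Both genes were printed in 1 subgrid of the array, which held 10 of all 51 calls where 0.994 are expected from its 259 genes (two-sided Fisher's exact p = 4.19e-08, adjusted p = 2.01e-06 over 48 subgrids). A total of 51 genes were called, 21 with a more positive and 30 with a more negative sex difference in genotype 2, and 780 had an unadjusted p under 0.05. These calls take samples as units, whereas genotype rests on 3 against 3 blocks. Tested on the sex differences of the blocks, limma called 0 genes (404 unadjusted, smallest adjusted p = 0.393). In the fit of samples 2 other divisions of the blocks called 83 and 983 of the genes measured in all samples, against 47 for the real one. Median centring within arrays gave 10 positive and 33 negative calls, and no normalization between arrays gave 25 and 58. Pglym78 was lost in 3 of 26 settings, with block means, without block 1 (adjusted p = 0.0585) and without the 7 arrays with many spots at 0 (adjusted p = 0.0691). Rab26 was lost in 5 of 26, with block means, with log-ratios and without block 3, 5 or 6. The call of mRpS14 was lost in 11 of 26: with block means, print-tip loess, quantile normalization, log-ratios, the authors' table, the quantification day, without the 7 arrays and without block 1, 3, 4 or 6. The count was 14 without block 6, 31 without block 2 and 152 without block 4, and 668 (171 and 497) without the 7 arrays with many spots at 0.

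The sex effect of 2 lists differed between the genotypes: digestive proteases (23 of 30 positive, adjusted p = 4.69e-05) and cytoplasmic ribosomal proteins (72 of 86 positive, adjusted p = 2.22e-06), both with adjusted p = 0.194 with an estimated correlation and with 0 members called over all genes. Both were lost with median centring (adjusted p = 0.055 and 0.52) and without block 4 (adjusted p = 0.0514 for both), and over 27 settings they ranged from 4.7e-07 to 0.194 and from 1.07e-15 to 0.52. Adjusted over the list alone, 2 digestive genes were shifted up and 1 down, 2 carbohydrate and 2 P450 or glutathione transferase genes down, 1 eggshell and 1 immune gene up and 1 fat body gene down. In the other lists the genes called over all genes were trk in the oocyte list (up) and Gld, Pglym78, mRpS14 and CycE (down), where the probe of trk was 1 of 104 displaced upwards or downwards in block 2 and that of CycE lay in the subgrid with 10 calls. Median, mean and test differed in sign for the male-enriched fat body, immune, heat shock, P450 and cuticle lists.

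The 5th question was whether the diet effect depends on the genotype. In the fit of samples the immune effector list was shifted (adjusted p = 3.87e-10 by cameraPR, or 0.00999 with an estimated correlation). That fit takes samples as units, whereas genotype rests on 3 against 3 blocks. Of the 49 genes, 31 had a higher diet effect in genotype 2, with a median difference of 0.09 and a mean of 0.32. When adjusted over the list alone 8 members were called, but 0 over all genes. The antimicrobial peptide genes Mtk (1.93, SE 0.397, adjusted p = 0.0732), AttA (1.92, SE 0.430, adjusted p = 0.119), DptB (1.65, SE 0.340, adjusted p = 0.0732), AttC (1.63, SE 0.395, adjusted p = 0.243) and DptA (1.51, SE 0.464, adjusted p = 1.00) had the largest differences. In genotype 2, Mtk had means of 9.87 (SD 1.17, n = 6) in females on the high and 8.58 (SD 0.616) on the low diet. In genotype 1 females the means were 9.28 (SD 1.30) and 10.25 (SD 0.654). With the sexes averaged, block 1 of genotype 1 also rose with the high diet, by 1.08 for AttA, 1.19 for AttC and 0.52 for DptB. In block 6 of genotype 2 these values were 0.82, 0.65 and 0.40. Mtk and DptA rose in block 1 too, by 0.70 and 0.19, and all of these genes fell in blocks 2 and 3. Within females the shift of the list had adjusted p = 2.64e-11 (0.00459 with an estimated correlation) and within males adjusted p = 0.00491 (but 0.585 with an estimated correlation). On block means the list had adjusted p = 0.0401. Over blocks the list median of high minus low was positive in 3 of 3 blocks of genotype 2 and in 1 of 3 of genotype 1, and an exact permutation test over the 6 blocks gave p = 0.4 for medians and 0.3 for means, where the smallest p it allows is 0.1.

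By single genes the genotype by diet interaction had 0 calls by limma, with 296 genes at an unadjusted p under 0.05. The count was 0 within females (300 unadjusted) and within males (283 unadjusted), and 0 for the interaction of all 3 factors (275 unadjusted). On block means it was 0 as well (792 unadjusted). Other settings called 0 to 10 genes, the latter with an intensity trend in the variance prior, and leaving out block 1 called 21. A further 4 lists passed at the preset correlation: respiratory chain (up, adjusted p = 5.11e-05), muscle (up, adjusted p = 0.0152) and ribosomal genes (up, adjusted p = 0.0447), each with adjusted p = 0.907 with an estimated correlation, and larval serum genes (down, adjusted p = 0.0447, or 0.0921 with an estimated correlation). Adjusted over the list alone, 1 lipid gene was shifted up. Median and test differed in sign for the eggshell and accessory gland lists.

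The last comparison was between the genotypes themselves. SmD3 (CG8427), which encodes a core protein of spliceosomal particles, was higher in genotype 2 (log2 difference 2.37, SE 0.159, adjusted p = 0.0352 by limma on block means, n = 3 blocks per genotype). Trm7-34 (CG7009), a transfer RNA methyltransferase gene, was higher too (2.32, SE 0.139, adjusted p = 0.0285), and CG10700, chosen after its value was seen, was at least 3.17-fold higher (adjusted p = 0.00847), because it did not exceed the blank spots in any sample of genotype 1. In genotype 1, SmD3 exceeded the blank spots in 10 of 24 and Trm7-34 in 4 of 24 samples, so the size of these differences is not resolved. Only these 3 genes were called, with 888 at an unadjusted p under 0.05, and none was lower. SmD3 and Trm7-34 were printed in the subgrid that held 10 of the genotype by sex calls, and without its genes 1 gene was called. Genes at an unadjusted p under 0.05 exceeded their share in 9 of 48 subgrids and fell below it in 16 (adjusted p under 0.05 in each). Each of the 3 calls was lost without any 1 of blocks 2 to 6, and 12 genes were called without block 1. The polymerase gene PolA1 (CG6349, 3.07, SE 0.249, adjusted p = 0.0608), printed in the same subgrid, Jon25Bii (CG8869, 1.41, adjusted p = 0.225), Cyp6g1 (-1.50, adjusted p = 0.379) and Cpr67B (CG3672, 0.80, adjusted p = 0.225) were not called. No list passed, the closest being the digestive protease and accessory gland lists (adjusted p = 0.0949 for both). Adjusted over the list alone, 4 digestive genes, 1 phototransduction gene and 1 cell cycle gene were higher and 1 carbohydrate gene was lower. Median, mean and test differed in sign in 10 lists: eggshell, sex determination, male-enriched fat body, insulin, lipid, muscle, phototransduction, odorant-binding, cytoplasmic ribosomal and respiratory chain.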

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

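The tests of the immune list and of 1 male sample, by print subgrid, on same-sex and mixed-sex arrays alone, on block means and without the 7 arrays with many spots at 0 were chosen after the results were seen. Of 70 groups of values examined, 6 held a sample or block that stood apart, where 3.5 are expected by chance. Its gap to the nearest other value was 0.634 of the range of the group for Npc2e and 0.651 for lncRNA:CR32368, each as the highest of 6 high-diet females of genotype 2. The gap was 0.628 for AttC as the lowest and 0.627 for DptA as the highest of 6 low-diet males of genotype 2, and 0.656 for DptB as the highest of 6 high-diet males of genotype 1. For the median diet effect of female-biased genes in males it was 0.655, with block 3 as the highest of 6 blocks, at 0.43.

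At the preset correlation the diet effect differed between the sexes in 7 lists: eggshell (adjusted p = 0.00338), oocyte (0.0168), testis (0.0168), larval serum (0.0438), immune (0.00338), odorant-binding (0.0137) and cytoplasmic ribosomal genes (0.00338), none of which passed with an estimated correlation. Signal of the partner sample on the same array is a candidate explanation for the wide spread of diet effects in the sex-biased classes between blocks (SD 0.314 for male-biased genes in females), since genes of the opposite sex were brighter by a median of 0.636 on mixed-sex than on same-sex arrays, in 22 of 24 pairs of samples (exact sign test p = 3.59e-05), while genes of the own sex had a median of -0.0628. That test takes the pairs as independent, although pairs share arrays. Partner signal might account for the whole spread of male-biased genes in females, which was 0.0228 on same-sex and 0.632 on mixed-sex arrays, but diets were compared within an array on the former and between arrays and with the dyes reversed on the latter, and genes of the opposite sex lay near the floor on the former, so other spread between arrays would look alike. For genes of the own sex the spread rose as well, from 0.0376 to 0.547 for male-biased genes in males and from 0.0395 to 0.300 for female-biased genes in females. Signal of a partner with little of these transcripts would change them little, so it need not be the whole cause. The 7 arrays with many spots at 0 are argued against as the whole cause, because the spread was still 0.306 without them. They were chosen by spots at 0 and not by brightness, so dim arrays stay open. By the yolk genes 1 male sample, of the low diet in block 6, lay nearer to the females, and 0 female samples lay nearer to the males by the accessory gland genes, so RNA of the other sex stays open for that sample, whose array was mixed-sex. A female sample in its place is argued against, because its accessory gland mean was 11.89, against 11.37 to 12.34 in males and 8.15 to 9.73 in females. A true difference between the sexes in their response to diet stays open as well and was not tested apart from these.

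The sex effect differed between the genotypes in 51 genes and in the lists of digestive proteases (adjusted p = 4.69e-05) and cytoplasmic ribosomal proteins (2.22e-06), both with adjusted p = 0.194 with an estimated correlation. On block means 0 of the genes were called. The 10 divisions of the 6 blocks are too few for a test: 3 of them, the real one included, called at least its 47 of the genes measured in all samples. The other 2 called 83, with blocks 1, 2 and 4 against the rest, and 983, with blocks 1, 5 and 6, which points to a structure of the samples other than genotype. Place on the printed array may account for the genes of 1 subgrid, in a corner of the array, which held 10 of the calls where 0.994 are expected, against 3 in the next subgrid, and where the block means of the genotypes correlated least across probes, at 0.808. Without the genes of the subgrid 36 genes were called, 13 with a positive and 23 with a negative interaction. Place on the array stays open for them too, since genes at an unadjusted p under 0.05 exceeded their share in 7 subgrids (highest adjusted p 0.0276) and fell below it in 5. A difference between the genotypes stays open, as does any other difference between the 2 sets of blocks, which the design joins to genotype.

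In the fit of samples the diet effect differed between the genotypes in the immune list (adjusted p = 3.87e-10, or 0.00999 with an estimated correlation). Within females it was 2.64e-11, or 0.00459, and within males 0.00491, but 0.585. The same fit called the larval serum (0.0447, or 0.0921), muscle (0.0152), cytoplasmic ribosomal (0.0447) and respiratory chain lists (5.11e-05), the last 3 with 0.907 with an estimated correlation. By single genes the real division called 0 and the highest other called 6, and the 10 divisions are too few for a test. For the immune list, probes close to the level of blank spots stay open. The 30 members above that level in a group had a median difference of 0.354, but which members these are depends on the groups that change. The 19 above it in at least 24 of 48 samples had 0.370, 14 of them positive, which missed the bar set for evidence against (exact sign test p = 0.0636). A single temporal block and a difference between the genotypes cannot be told apart: the median difference of 0.0866 kept its sign without each block in turn, which had been set as evidence against a single block, but its lowest value of 0.0272 lay below the standard error of 0.0715. The genotypes themselves, and any difference in the microbes or handling of the blocks that the design joins to them, stay open and were not tested.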

How the results depend on the processing

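Settings with spots at 0 left out, the filter against blank spots, the 7 arrays with many spots at 0 left out, the quantification day, 1 kind of array, the genes of 1 print subgrid left out, the displaced genes left out and block means for interactions with genotype were chosen after the data were seen. Signal over background limits all results, since 10.7% to 51.6% of gene spots exceeded the blank spots. Of the values of single genes, 3007 kept their direction and call, 57 lost and 31 gained a call and 3 turned; of those of lists, 834 kept and 133 lost their call and 10 turned. For sex, 1941 values of genes and 463 of lists were kept and 17 of lists were lost, 11 of them for insulin and TOR genes. The count for sex was 4550 with the filter against blank spots, which tests fewer genes, and 5194 on same-sex arrays, which are fewer. For diet in females (2 genes) it was 0 with quantile normalization, with log-ratios and in genotype 1 or genotype 2 alone, 1 with no background correction, the authors' table, bad spots kept or the quantification day, and 0 to 10 without 1 block. For diet in males (0) it was 1 in the authors' table, 2 with no background correction, an intensity trend or the blank filter, 3 without the 7 arrays, and 0 to 11 without 1 block. For sex by diet (0) it was 1 without the 7 arrays. For genotype by sex (51) it was 89 with no background correction, 83 with no normalization between arrays, 107 with quantile normalization, 25 with log-ratios, 121 in the authors' table, 668 without the 7 arrays, 33 with the quantification day, 0 on block means, and 14 to 152 without 1 block. For genotype by diet (0) it was 1 with print-tip loess, no normalization between arrays or bad spots kept, 2 with no background correction, spots at 0 left out or the 7 arrays left out, 4 with the strict filter, 6 with the blank filter, 10 with an intensity trend, and 0 to 21 without 1 block. For genotype (3) it was 17 with no background correction, 22 with no normalization between arrays, 6 with the strict filter, 11 in the authors' table, 5 with bad spots kept, 141 with single samples and the block as random, 9 with the blank filter, 1 without the genes of 1 print subgrid, which held 2 of the 3, and 0 to 12 without 1 block. The median diet effect of female-biased genes in males turned to 0.0233 with median centring, 0.0135 with quantile normalization, and 0.00360, 0.0177 and 0.00343 without block 1, 2 or 4, and ranged from -0.108 to 0.0177 without 1 block. That of male-biased genes in females turned to -0.0626 with median centring, -0.00991 with no fold minimum, -0.0149 on same-sex arrays, where diet goes with dye, and -0.0798 and -0.0493 without block 3 or 5, with 0.0803 as the highest without 1 block, and that of male-biased genes in males passed at 0.172 in the authors' table. In genotype 1 alone the diet effect of yl in females was -0.0202 and that of Yp1 in males 0.0763, and the sex by diet value of Yp1 was -0.0339. The diet effect in females of the eggshell and ribosomal lists turned in genotype 1 alone (adjusted p = 0.656 and 0.809) and that of the oocyte list without the 7 arrays (0.49). The sex by diet shift turned in genotype 1 alone for the eggshell (0.0914), oocyte (0.942) and testis lists (0.892), and without the 7 arrays for these (0.279, 0.00235 and 1.15e-05) and the odorant-binding list (0.804). Apart from the tested numbers of genes and arrays named here, the cause was not tested. The filter on the local background removed only 2 probes, so running without it tests nothing. Genotype was not run without the 7 arrays, which left unequal samples per block, nor with the quantification day or 1 kind of array.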

Other observations

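Further genes of lists that did not pass as sets also differed by sex. Jon99Fi (CG18030), which encodes a digestive serine protease, was 2.29-fold higher in females (log2 difference 1.19, SE 0.142, adjusted p = 4.31e-09, 6 of 6 blocks), and exceeded the blank spots in 2 of 12 males on same-sex arrays. Lsp2 (CG6806), which encodes a larval serum protein, was 1.81-fold higher in males (log2 difference -0.86, SE 0.126, adjusted p = 3.05e-07, 6 of 6 blocks), with 4 of 12 females above the blank spots on these arrays, and Hsc70-2 (CG7756), of the heat shock cognate family, was at least 2.44-fold higher in males. By chromosome, genes at least 2-fold higher in males made up 3.57% of the 2047 genes on the X and between 5.43% and 7.10% of those on the 4 large autosomal arms. Genes at least 2-fold higher in females made up 4.40% of those on the X and between 3.19% and 3.79% on these arms. On chromosome 4 they numbered 3 and 2 of 79.

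The tests by temporal block and print position and those without the 7 arrays with many spots at 0 were chosen after the results were seen. In block 2, 104 genes had a mean over 2 log2 units from that of the nearest other block, 96 higher and 8 lower, against 2 in block 1, 3 in block 3 and 0 in blocks 4 to 6. Among them thoc6 (CG5632) had a mean of 13.93 in block 2 and of at most 8.91 in the others, and Act5C (CG4027), which encodes an actin, of 7.85 and at least 13.20. They lay in 18 print subgrids, in large part in 5 of them, and without them 8009 genes were called for sex, 50 for genotype by sex and 3 for genotype. In block 2 Act5C had an SD of only 0.0591 over 8 samples, and RpL21 (CG12775) a mean of 7.83 (SD 0.0260), against 11.80 to 13.69 elsewhere. In 1 subgrid block 2 correlated with the other blocks of its genotype at 0.702, against 0.837 to 0.988 for the other blocks. Further probes may thus be affected. Whether the displaced values measure the named genes was not tested.

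In the subgrid that held 10 of the genotype by sex calls, 63 of 259 genes had an unadjusted p under 0.05 for genotype (adjusted p = 2.93e-18 over 48 subgrids), and a subgrid in another corner had 60 (adjusted p = 4.95e-14). Such genes exceeded their share in 9 of 48 subgrids, with 35 to 63 genes in each and a highest adjusted p of 0.00169, and fell below it in 16. For genotype by sex they exceeded it in 7, with 28 to 51 genes, and fell below it in 5. The same subgrid held 121 calls for sex, where 157 are expected (adjusted p = 0.000214).

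For sex, 1 of 100 divisions of the samples, the real one, called as many as 7913 genes measured in all samples, and the highest other called 2921. This argues against chance for the count, although 1 of 100 is the smallest share these divisions can give. For diet in females 6 of 100 divisions called as many as the real one, with 8 in the highest other, so chance cannot be excluded for the 2 calls. For diet in males and for sex by diet the real division called 0, so all 100 divisions called as many and the comparison decides nothing. The highest other called 245 in males, which points to a structure of the samples that was not tested further, and 7 for sex by diet. For genotype the 10 divisions are too few for a test; the real one called 3 genes and the highest other 0. Of simulated changes of 1.5-fold with diet, 84% were called in each sex, and without the 7 arrays with many spots at 0 at most 3 genes were called for diet in a sex. The simulated data held no spread of effects between blocks, so 84% may be too high for the real data.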
